A study of Homo sapiens with 2 samples.

How the data were processed

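Total RNA of A2780 cells was extracted with Trizol, and a linker carrying the dye DY547 was ligated to it, per the labels' protocols. The labelled RNA was hybridized as channel 1. Channel 2 held labelled DNA oligonucleotides that match some mammalian miRNAs. Per the labels, the submitters left this reference channel out of their analysis. There was 1 control array and 1 hypoxia array, assigned by their titles. Whether the cells of each array came from one culture or from pooled cultures was not given in the sources used here.

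The deposited intensity values are spot amplitudes made with BlueFuse for Microarrays 3.4, per the file headers. Each array held 4704 spots, all included, and spots with the same name were combined by their mean into 1147 names, about 4.1 spots per name. No normalization setting was recorded in the headers, and the treatment of the background was not given in the sources used here. The deposited files also give, as a fraction from 0 to 1, the software's probability that a channel carries signal. The log2 ratio of the channels and the SD of that ratio among the spots of a name were deposited as well, per the file headers. The files used here hold no values of single spots or of the local background.

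The series also holds a deposited table with 1 score per probe and array, whose making is not described. Set against the amplitudes, this score was a straight line of the channel 1 amplitude of the same array, with a largest residual of 0.0052. It was 0 at an amplitude of 306.0 on the control array and 234.0 on the hypoxia array, which is the amplitude of the probe named unknown, and 1 unit was 338.1 and 331.2. The score is therefore linear and not log2, its medians were 0.35 and 0.39, its upper quartile was 1.0 on each array, and 308 and 252 of its values lay below 0. Why the probe named unknown was taken as 0 is not given in the sources used here.

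Channel 1 amplitudes were background-corrected with normexp and an offset of 50 and quantile-normalized between the arrays with limma 3.58.1 in R 4.3.3, without the 3 control names. They were then taken to log2. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A probe was called detected when its probability of signal in channel 1 was at least 0.5. Where a probe was detected on 1 array only, the fold is a lower bound against the higher of its own level and the lowest level of a detected probe on the other array, 8.16 (log2) on the control array and 8.42 on the hypoxia array. That floor leaves out amplitudes that differ from the channel sum, a choice made after the data were seen. With them the floor on the hypoxia array was 7.57, set by a rat miR-382 probe. Where a probe's own level lay above the floor, its bound is the plain fold and no assured minimum. The names fell into 467 human miRNAs, 403 of other vertebrates, 182 of worms and insects alone, 76 numbered probes, 16 other RNAs and 3 controls. Probes listed first under a worm or fly name but not named for worms and insects alone, such as fly miR-184, were counted with the other vertebrates. On each array 1 amplitude carried a question mark, miR-451 on the control array and a mouse miR-488 probe on the hypoxia array, and these were left out, with their use as an alternative. miRNA names are those of the array's design, and closely related family members can share signal on such probes.

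Since there was 1 array per condition, no test and no error between cultures could be computed, and the number of arrays limits the precision. The SD among spots of a name describes the printing and hybridization of 1 array. Its median over detected human probes was 0.39 on the control array and 0.33 on the hypoxia array. Among those with channel 2 on it was 0.2 (44 probes) and 0.15 (35 probes). As an SD of the channel ratio it also holds the spread of channel 2 and does not measure the spread of channel 1 alone. Each fixed list was described by the median difference of its detected probes and by the percentile of that median among 10000 random lists of the same size, each member drawn from the 60 probes nearest in mean log2. Random members were drawn independently, whereas probes of one family can share signal. Percentiles of family lists can therefore lie further out than those of unrelated probes, and they were not adjusted for the number of lists. In all, 23 lists were fixed and 21 had a detected member. The lists, the settings, the alternatives and the rule for named miRNAs were fixed before the data were examined. That rule took human probes detected on at least 1 array with a difference of 2-fold or more, the 12 largest in each direction. It added every detected member of the miR-199 and miR-214 list, miR-210, up to 4 members of each other list with the largest and smallest differences, and the 5 brightest of each array. The rule also asked that the spots of the arrays not overlap, which could not be applied because the files used here hold no single spots. Detection was planned on local background and used the software's probability in its place for the same reason.

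The calculation was tested on simulated data, with 200 of 1146 probes changed by known amounts. With noise like that of the reference channel (SD 0.71), 93.0% of 4-fold changes and 55.0% of 2-fold changes passed 2-fold, and 18.3% of unchanged probes did so too. With noise of SD 0.24 these shares were 100.0%, 41.0% and 0.0%. Human gene neighbours were taken from RefSeq genes of assembly GRCh38.p14, used only for names and neighbours, in which 374 of 422 human miRNA names were found.

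The alternatives were no background correction, an offset of 16, no normalization, equal medians of detected probes, equal upper quartiles, loess, no detection filter, detection on both arrays, the ratio to channel 2 (with the median of 0.51 over 38 probes subtracted), the deposited table floored at 0.25, a 1.5-fold threshold, averaged arms and kept question marks. Added after the data were seen were amplitudes recomputed as the channel sum minus channel 2 and the probes with channel 2 off on both arrays.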

Results

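A2780 is a human epithelial ovarian cancer cell line. Its small RNAs were profiled on 2 spotted microRNA arrays, 1 of cells kept in a standard incubator (control) and 1 of cells held for 48 h in a chamber at about 3% oxygen (hypoxia). The title of the series names the question, which is the part miR-199 plays in the response to hypoxia that runs through the transcription factor HIF1A. Each array held 467 human miRNA probes. Signal was called for 176 of them (37.7%) on the control array and for 166 (35.5%) on the hypoxia array, and the channel carrying the sample had a signal-to-background ratio of 13.82 and 17.4. With 1 array per condition there was no replicate, no difference could be tested, and every difference below describes these 2 arrays. Differences are hypoxia minus control on the log2 scale of the normalized amplitude, and miRNA names are those printed on the array.

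On the hypoxia array 22 of the 206 detected human miRNA probes were at least 2-fold higher than on the control array and 17 were at least 2-fold lower. The largest difference upward was at miR-320, whose amplitude was 1031 on the control array and 7920 on the hypoxia array (log2 difference 3.06). Downward, miR-363*, the minor arm of a miRNA of the miR-106a-363 cluster, had 14839 on the control array and 1019 on the hypoxia array (log2 difference -3.75). The other arm did not share this drop, with 0.36 at miR-363, 0.24 at a mouse miR-363 probe and 0.09 at a rat miR-363-3p probe. These probes were named after their values were seen. miR-29c (-2.94) and miR-29a (-1.78), which repress collagens and other extracellular matrix genes, were lower. miR-494 of the imprinted DLK1-DIO3 region (1.57), miR-19a of the miR-17-92 cluster (1.67) and miR-214 (1.59) were higher. Without normalization between the arrays the split was 19 higher and 22 lower, with the median of the detected probes at -0.19 in place of -0.04.

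Of the 22 higher probes, 12 were detected on both arrays, among them miR-320, miR-202 (2.21), miR-561 (1.66), miR-19a, miR-214 and miR-494. The remaining 10 were called only on the hypoxia array, so the fold is a lower bound. miR-515-5p was at least 2.59-fold higher, miR-367 at least 2.51-fold, miR-526a at least 2.15-fold, miR-302c* at least 1.96-fold, miR-518f* at least 1.87-fold and miR-614 at least 1.69-fold. At these bounds 16 probes stayed 2-fold higher. Among the 17 lower probes, 8 were detected on both arrays, including miR-363*, miR-29c, miR-29a, miR-594/tRNA (-1.79), miR-487b (-1.43) and miR-93 (-1.37). The other 9 were called only on the control array, and 13 of the 17 lower probes stayed past 2-fold at their bounds. miR-769-3p was at least 2.42-fold lower on the hypoxia array and miR-513 at least 2.1-fold. For miR-633 (4.1-fold lower) and miR-92b (3.06-fold lower) the probe's own level on the hypoxia array lay above the floor. Their folds are the plain differences. The bounds of miR-95 (1.89-fold), miR-542-5p (1.87-fold) and miR-98 (1.42-fold) were below 2-fold. The deposited amplitudes of miR-202, miR-633 and miR-542-5p did not match the files' own channel sums, nor did that of miR-198 (1.37), which is counted among the 12 higher probes detected on both arrays. With amplitudes taken from those sums the log2 differences were 1.51 for miR-202, -1.66 for miR-633, 1.41 for miR-542-5p and -0.05 for miR-198. This turned the direction of miR-542-5p and left miR-198 short of 2-fold. miR-198 was named after its values were seen.

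**Figure D1:**
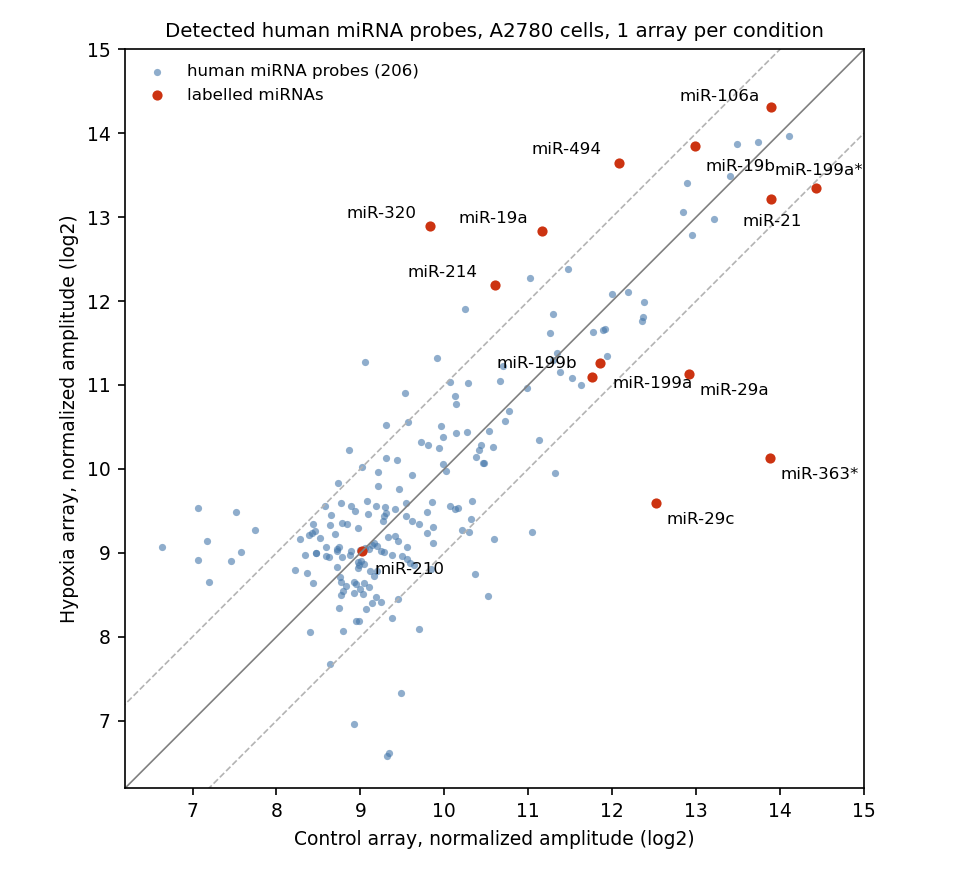
Normalized amplitude (log2) of the 206 human miRNA probes detected on at least 1 array, with the control array on the x axis and the hypoxia array on the y axis. Each point is 1 probe, the solid line marks equal values and the dashed lines a 2-fold difference. miR-320 lies 3.06 above the line of equal values and miR-363* lies 3.75 below it (log2 difference -3.75).

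The brightest human probes on the control array were miR-199a*, miR-17-5p, miR-21, miR-106a and miR-363*, and on the hypoxia array miR-106a, miR-17-5p, miR-20a, miR-20b and miR-19b. miR-21, a widely described oncogenic miRNA, had an amplitude of 15018 on the control array and 10003 on the hypoxia array (log2 difference -0.68). miR-106a differed by 0.42, miR-20a by 0.16, miR-20b by 0.38, miR-19b by 0.86 and miR-17-5p by -0.14. The miR-20b probes of other species were lower instead, with -0.19 at zebrafish, -0.51 at mouse and -1.41 at rat, named after their values were seen. For miR-17-5p the sign depended on the scaling, with 0.14 when the medians of the detected probes were set equal. Amplitudes of different probes do not rank the abundance of their miRNAs.

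All 3 human miR-199 probes were lower on the hypoxia array, and miR-214, whose gene lies within 10 kb of a miR-199a gene, was higher. miR-199a*, the name then used for the 3' arm, had the highest amplitude of any human probe on the control array, 18671, against 10983 on the hypoxia array (log2 difference -1.07, 2.11-fold lower). The 5' arm probes differed less, by -0.6 at miR-199a (3911 against 2252) and by -0.66 at miR-199b (3652 against 2119). A mouse miR-199b probe on the same arrays differed by -1.31. miR-214 had 1733 on the control array and 4387 on the hypoxia array, a log2 difference of 1.59 (3.01-fold). The 4 human probes of the list had a median of -0.63, at the 3.2 percentile of 10000 random lists of the same size and brightness. Those lists were drawn probe by probe and do not hold the signal that related miR-199 probes can share. Set against the reference channel, which only miR-199a and miR-214 allowed, the median was 0.26. The size at miR-199a* depended on the scaling: it was -0.61 when the medians of the detected probes were set equal. Spots printed with the same name differed on 1 array by an SD of 0.38 and 0.42 (log2 channel ratio) at miR-199a*, 0.08 and 0.07 at miR-199a, and 0.4 and 0.24 at miR-214. Channel 2 was off at miR-199a* (139 and 150) and on at miR-199a (6566 and 3719). These SDs therefore do not compare the spread of the sample signal between the 2 probes.

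miR-210, the miRNA most often described as induced by HIF, had nearly the same normalized level on both arrays. Its amplitude was 571 on the control array, where the probability of signal was 0.44, and 494 on the hypoxia array, where it was 0.76. The log2 difference was 0.01, and it lay between -0.16 and 0.02 under the alternative settings. Probes of other species called on both arrays, named after their values were seen, went both ways, with -0.47 at zebrafish miR-210, 0.14 at fly miR-210 and 1.06 at zebrafish miR-210*.

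Among 27 probes for miRNAs described as regulated by hypoxia or HIF, 21 were detected, with 16 lower and 5 higher on the hypoxia array. Of these 5, miR-210 and miR-424 (0.03) changed sign with the scaling, and miR-26a (0.09) had the lower raw amplitude on the hypoxia array (4288 against 4192). The median was -0.24, at the 5.0 percentile of random lists, and -0.51 without normalization between the arrays. Only miR-93 of this list passed 2-fold (-1.37). miR-181a was at least 1.48-fold lower, and the highest values were 0.55 at miR-195 and 0.42 at miR-106a. Set against the reference channel, miR-195 was -0.02. miRNAs described as binding HIF1A, EPAS1, ARNT or regulators of HIF had 14 of 20 probes detected, 7 on each side of 0. Their median was -0.01 at the 54.4 percentile, with a sign that changed with the scaling. In this list miR-335 (0.99) and miR-18a (0.92) were the highest and miR-199a* (-1.07) the lowest. The lists share members, such as miR-199a*, miR-424 and miR-107.

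The miR-29 family had the lowest median of the 21 lists with a detected probe, with 3 of 3 probes detected, a median of -1.78 and the 0.5 percentile. Its human probes did not move together, since miR-29b was 0.21, but a zebrafish miR-29b probe was -0.59. The median is the value of miR-29a, whose zebrafish probe gave -0.14. Both zebrafish probes were named after their values were seen. The list of the miR-17-92 cluster, which MYC and E2F activate, and of related miRNAs had 16 of 17 probes detected. Their median was 0.04 (64.7 percentile, and -0.07 without normalization). miR-19a was the only member of this list at least 2-fold higher, while miR-363*, miR-92b and miR-93 were at least 2-fold lower. The let-7 family and miR-98, repressors of RAS and HMGA2, had 8 of 9 probes detected and a median of 0.28 (82.0 percentile). Its values reached from miR-98 at the low end to let-7e (1.4) and let-7a (0.6) at the high end. The miR-183, miR-96 and miR-182 cluster had 3 of 4 detected, all higher (median 0.47, 82.0 percentile), with miR-96 at 0.8 and miR-183 at 0.11, which was -0.13 without normalization. In the imprinted 14q32 region 9 of 42 probes were detected (median -0.05, 45.5 percentile). There miR-494 (1.57) and miR-410 (0.83) were higher, and miR-487b (-1.43) and miR-493-3p (at least 1.94-fold) were lower.

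Other families lay mostly below 0 and held no member past 2-fold. All 5 probes of the miR-125, miR-99 and miR-100 list were detected and lower (median -0.39, 14.5 percentile), with miR-100 at -0.64 and miR-125b at -0.09. All 5 probes of the miR-23, miR-27 and miR-24 list were detected and lower (median -0.23, 26.1 percentile), from -0.71 at miR-27b to -0.08 at miR-23b. The miR-15, miR-16 and miR-195 family, repressors of BCL2 and cyclins, had 6 of 7 detected (median -0.35, 11.5 percentile), with miR-15a at -0.78, miR-16 at -0.6 and miR-195 at 0.55. miR-30 had 5 of 7 detected (median -0.24, 24.6 percentile), and miR-30c was the lowest at -0.44. miR-181 had 2 of 5 detected, miR-181a and miR-181c (median -0.76, 5.7 percentile, and -0.64 with both at their bounds). Of the miR-34 family, targets of p53, only miR-34b was detected (1 of 4 probes, -0.83). Both probes of the CDKN1B repressors miR-221 and miR-222 were detected, with 0.16 and 0.04 (median 0.1, 61.6 percentile, and -0.13 without normalization). Set against the reference channel, the sign turned upward at miR-21 (0.29) and miR-16 (0.59). It turned downward at miR-195 (-0.02, but 0.49 without the centring) and at miR-30a-5p (-0.84 in place of 0.18). None of the 7 probes of the epithelial miR-200 and miR-141 list was detected on either array, although 2 probes of other species for this family, zebrafish miR-200c (192 against 601) and mouse miR-429 (694 against 465), were called on the hypoxia array.

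**Figure D2:**
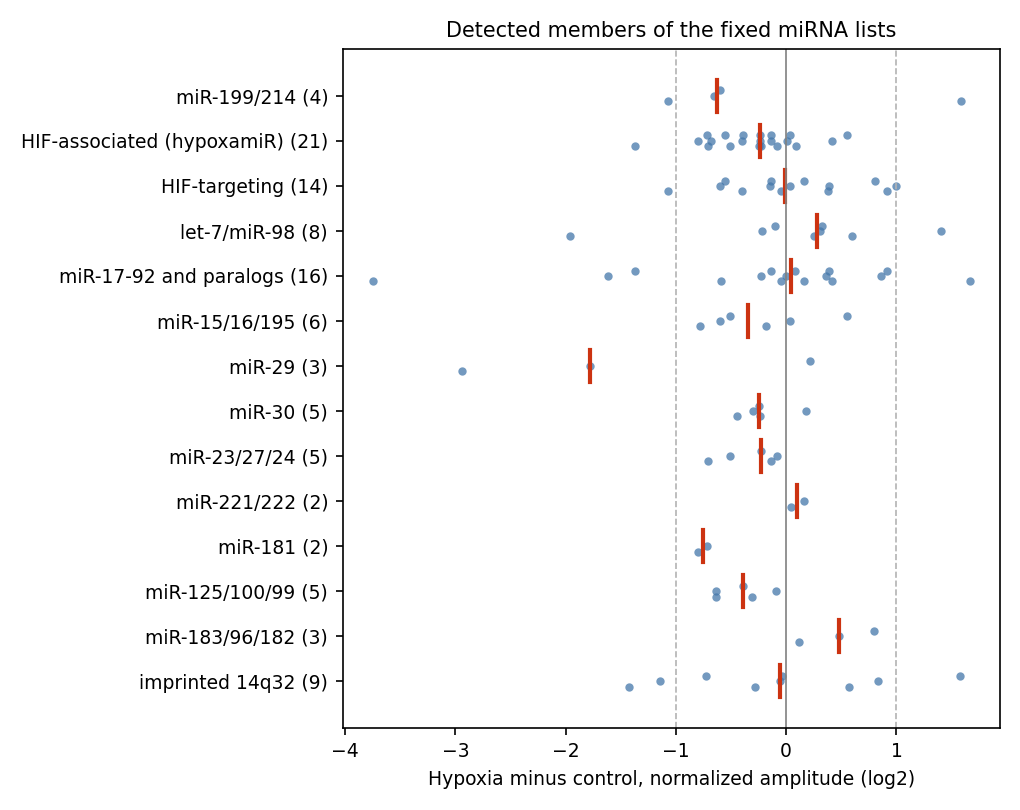
Hypoxia minus control (log2) on the x axis for the detected probes of each fixed miRNA list, 1 row per list with the number of detected probes in brackets. Points are single probes, red bars are list medians and dashed lines mark a 2-fold difference. The miR-29 list has the lowest median (-1.78), and the miR-199 and miR-214 list holds 3 probes below 0 and miR-214 at 1.59.

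Markers of other cell types were mostly not detected. Of the muscle markers 2 of 5 were called, miR-206 (1.22) and miR-1 (0.76), with a median of 0.99 at the 97.9 percentile. Embryonic and placental markers had 5 of 17 called (median 0.53, 92.9 percentile), led by miR-367 and miR-302c*. Blood markers had 2 of 7 called, miR-486 and miR-142-5p, both only on the hypoxia array (median 0.71, 94.4 percentile). This leaves out the blood marker miR-451, whose control amplitude carried a question mark: it was called on the control array only, with 1577 there and 205 on the hypoxia array. The stromal marker miR-143 was called on both arrays (1 of 2 probes, 0.37). The endothelial marker miR-126 was called on the control array only (1 of 2 probes, 383 against 257), too near the floor to give a fold. Neural markers had 3 of 5 called (median -0.15, 37.0 percentile, and 0.41 among probes with the reference channel off). Of these, miR-9 was 1.55-fold lower by its plain difference, and miR-9* was at least 1.41-fold higher. The single liver probe was not detected.

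The profiles of the 2 arrays correlated across the 206 detected probes (Pearson r 0.8, Spearman rho 0.71), which are not independent replicates. Probes for worm and insect miRNAs with no human counterpart number gave the background for the differences. Of the 52 that were called on at least 1 array, 9 (17.3%) passed 2-fold, 7 higher and 2 lower, against 39 of 206 human probes (18.9%). Among probes called on both arrays, 4 of 26 worm and insect probes (15.4%) and 20 of 135 human probes (14.8%) passed 2-fold. The differences of these 26 ran from -1.89 to 2.38, and those of all 52, some not called on the control array, from -2.15 to 3.29. miR-363* and miR-29c lay below both ranges, and miR-320 lay above the narrower one only. No other of the 135 human probes called on both arrays lay outside the narrower range. Of the 206 human probes 5 lay below the wider range (miR-363*, miR-29c, miR-95, miR-513 and miR-542-5p) and none above it. With more human than background probes, some can lie outside even if all were alike. Lying outside therefore does not by itself set a probe apart from the background. The miR-199 probes and miR-214 lay inside both ranges. The ends of the narrower range were set by bright probes, worm miR-357 (27920 against 8550) and worm miR-265 (2302 against 11456). The next probes inside it were worm miR-270 at -0.96 and worm miR-256 at 1.25. miR-199a* (-1.07) and miR-214 (1.59) lay beyond those, but worm miR-270 (865 against 381) and worm miR-256 (402 against 783) were dimmer than both. Worm miR-357, about as bright as miR-199a*, differed by -1.89. The background at the brightness of miR-199a* and miR-214 rests on few probes, so it does not show that these 2 exceed it.

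**Figure D3:**
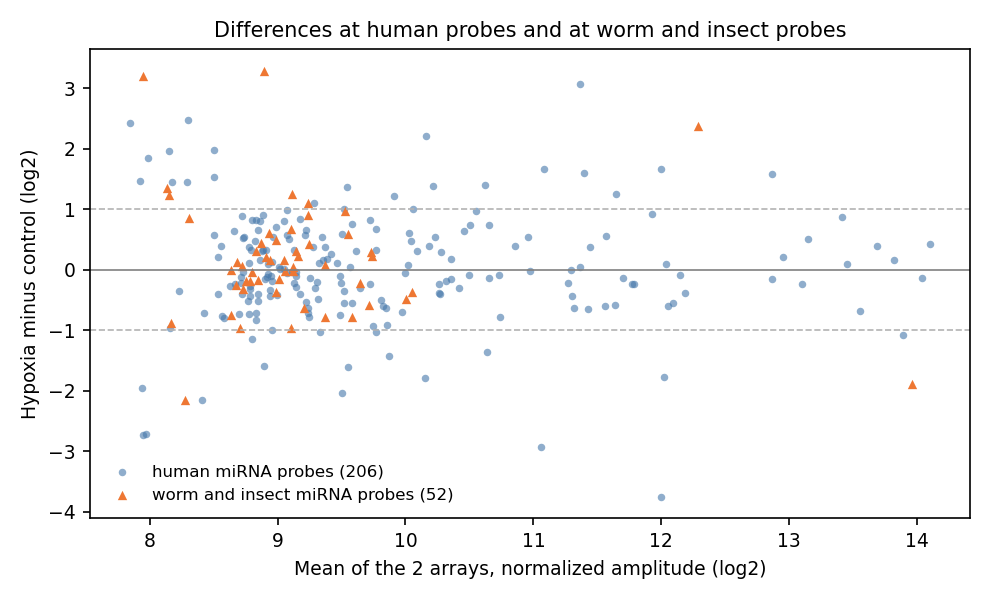
Hypoxia minus control (log2) on the y axis against the mean normalized amplitude of the 2 arrays (log2) on the x axis, for 206 human miRNA probes (circles) and 52 worm and insect miRNA probes (triangles) detected on at least 1 array. Dashed lines mark a 2-fold difference. Of the triangles 17.3% lie outside the dashed lines, against 18.9% of the circles.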

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

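For the human and worm differences, for miR-199 and miR-214 and for rounding, the tests were chosen after the values were seen, whereas the test of replaced values against the spread of spots was written down first. Signals outside the human miRNA probes stood above the control array at these probes. The 28S ribosomal RNA probe, shared with a zebrafish miR-739, differed by 1.79, with 8599 on the control array and 33583 on the hypoxia array, its brightest value. The small nucleolar RNA U49 differed by 2.01 (2322 against 9323), and the small RNA 5SN1 by 1.05 (833 against 1375). Among worm and insect probes without a human counterpart number, 7 were detected on the hypoxia array and at least 2-fold above the control array, the brightest of them the worm miR-265 (2302 against 11456), and 4 of the 7 were not called on the control array.

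The number of human probes past 2-fold may come from the spread between 2 arrays. Worm and insect probes without a human counterpart number passed 2-fold in 17.3% of 52, against 18.9% of human probes, so probes with no intended target in these cells passed it about as often. Low signal as the whole cause is argued against by the bright human probes, of which 25% (10 of 40 with a mean log2 of 11 or more) passed 2-fold. At the middle brightness of the worm and insect probes, 2 of 61 human probes (3.3%) and 3 of 26 worm and insect probes (11.5%) did so. Hypoxia stays open as a cause and was not tested, since array and condition cannot be separated with 1 array each, and worm and insect probes could also bind human RNA.

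The human miR-199 probes were lower and miR-214 higher on the hypoxia array. At miR-214 the reference channel, relative to its own median, differed by 0.17 against 1.59 in the sample channel. That gap of 1.42 lay within 2 SDs of such gaps over 38 probes (SD 1.21), so a printing or hybridization difference at the probe was neither excluded nor borne out. At miR-199a the reference channel differed by -0.51, against -0.6 in the sample channel, so such a difference was neither excluded nor borne out there either. The SD of 1.21 contains the sample differences themselves and exceeds the SD of the sample differences over the 206 detected probes (0.94). Most gaps lie within such a width, so the test could decide little at either probe. The median of the 4 miR-199 probes, a mouse probe included, lay at the 3.2 percentile of random sets of like brightness, inside the central range set for that test, so the spread of single probes stays open, as does an effect of low oxygen, which was not tested.

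Deposited channel 1 amplitudes of 41 entries (27 on the control array and 14 on the hypoxia array, at 37 probes) were whole numbers that differed from the channel sum minus channel 2 by more than 0.01. Rounding is argued against by the size of the gaps, with a median of 408.9 and 418.8 amplitude units and a smallest gap of 120.8. The log2 channel ratio of these names spread more among spots than that of others. Its median SD was 2.09 against 0.72 on the control array and 2.25 against 0.65 on the hypoxia array. Both medians lay at the 100 percentile of random sets of rows. Those sets were not matched on brightness or on channel 2 signal, so this does not show that the channel 1 spots themselves disagreed. A candidate explanation is that values were replaced where the spots disagreed, by a step the headers do not record, and no biological explanation was tested. The entries include the probe named unknown on the hypoxia array (234.0 against 458.2), which is the 0 of the deposited table.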

How the results depend on the processing

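The alternatives on recomputed amplitudes, on probes with channel 2 off and on the floor of the bounds were chosen after seeing the data. Under all settings that gave them a value, miR-199a* (-0.61 to -1.08), miR-199a, miR-199b and miR-214 (1.0 to 1.61) kept their direction, and only the ratio to channel 2 lacked miR-199a* and miR-199b. That ratio was centred by 0.51, and uncentred miR-199a was 0.02 in place of -0.49. With replaced amplitudes allowed as the floor, 17 in place of 13 lower probes passed 2-fold at their bounds. The counts higher and lower by 2-fold were 22 and 17. They became 55 and 42 with no detection filter, 12 and 8 with detection on both arrays, 7 and 8 for the ratio to channel 2 (38 probes), 46 and 39 in the deposited table and 46 and 42 at 1.5-fold, and 11 and 12 among the 149 probes with channel 2 off. The filters and the threshold change which probes are counted. The deposited table subtracts the amplitude of the probe named unknown, which can widen log2 differences at dim probes, and how much of its count comes from this was not tested. For the ratio the cause was not tested. For the ratio to channel 2, list medians were 0.26 for miR-199 with miR-214 (only miR-199a and miR-214 had a ratio), 0.39 for 3 miRNAs binding HIF and its regulators, -1.12 for miR-17-92 (miR-18a and miR-93), 0.28 for miR-16 with miR-195 of the miR-15 list, -1.02 for miR-30, -2.57 for blood markers (miR-451 alone, left out of the main setting) and 1.77 for embryonic and placental markers (miR-367 and miR-517c). The deposited table gave -0.49 for the hypoxia-regulated list, -1.93 for miR-34, -1.45 for miR-181, 1.51 for blood and 1.17 for embryonic and placental markers. With no filter miR-34 was -0.19 and blood 0.12, with detection on both arrays 14q32 was 0.26, and without normalization the hypoxia-regulated list was -0.51. Among probes with channel 2 off, neural markers were 0.41 and embryonic and placental markers 0.1. With recomputed amplitudes miR-542-5p reversed to 1.41, since its deposited value was one of the whole numbers. The cause of the other shifts was not tested. Of the remaining values, 359 on the main comparisons and 824 on single miRNAs stayed within their spread, and 17 on single miRNAs moved beyond it. No paired analysis was possible because each condition had 1 array. Local background subtraction, the median of spots, another spot statistic and the count without overlapping spots were not run, since the files used here hold no single spots or local background. Signal over background limits dim miRNAs such as miR-210.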

Other observations

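Other small RNAs on the arrays also differed in both directions. The spliceosomal RNA U6, often used as a loading reference, had 5814 on the control array and 1388 on the hypoxia array (log2 difference -1.85), and it was not used for scaling here. The nucleolar RNA E1 was lower (9944 against 2325, -2.06), U47 was 9255 against 7536 (-0.42), and U46 was 1319 against 2228 (0.98). A probe added to the array for miR-21 gave -0.34, beside -0.68 at the standard miR-21 probe. The worm miR-357 probe had the highest amplitude of the control array, 27920, against 8550 on the hypoxia array. These 6 RNAs and the probes of the pairs below were chosen after their values were seen.

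Whether probes with the same miRNA name from different species differed alike was a prediction written before its result, while the strict match of name and arm and the limit to probes called on both arrays were set afterwards. Over 64 pairs with the same name and arm the differences correlated (r 0.67, across probes), at the 100 percentile of shuffled pairs, with the same sign in 46 pairs and a median gap of 0.4. Over the 48 pairs with both probes called on both arrays r was 0.63, with the same sign in 33. The human and mouse probes gave 1.57 and 2.39 for miR-494, -1.43 and -1.46 for miR-487b, and 2.21 and 2.45 for miR-202, whose human value was 1.51 with the recomputed amplitude. Some pairs of human and zebrafish probes parted, with miR-29a at -1.78 and -0.14, miR-29b at 0.21 and -0.59, and miR-93 at -1.37 and 0.39. Human miR-20b (0.38) parted from its zebrafish (-0.19), mouse (-0.51) and rat (-1.41) probes, and miR-16 (-0.6) from the chicken probe (0.17). A candidate explanation for the agreement is that the probes of a pair read the same RNA of the sample, which speaks for the array and not for the condition.

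A hypothesis, also written before its result, was that miRNA genes within 10 kb of each other, which may share a transcript, differ alike. Over 120 pairs of 86 miRNAs the mean gap was 1.09 against 1.1 after shuffling, at the 45.9 percentile, which decides neither way. miR-30b and miR-30d were both at -0.24, while miR-106a (0.42) and miR-363* (-3.75) of one cluster lay far apart. So did the human probes of miR-29b (0.21) and miR-29c (-2.94), though a zebrafish miR-29b probe gave -0.59.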
